A study of Glycine max with 12 samples.

How the data were processed

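Polyadenylated RNA from immature seed coats of 2 soybean lines was sequenced in 12 libraries, 3 for each of 4 groups made of a line and a dissected region. Per the labels, seeds weighed 100 to 200 mg, the coats were cut into the parts that would turn into the black saddle and the yellow sections, the tissue was freeze-dried, and the extraction was adapted to keep procyanidins from binding RNA. The libraries were sequenced on an Illumina HiSeq instrument, per the labels' protocols. The submitters' processing notes name Bowtie 1 as the aligner. The genome build, the annotation version, the treatment of reads with several hits and the strandedness of the libraries are not given in the sources used here.

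The deposited table held RPKM values, made by the authors, for 88647 transcript models of 56044 genes, with coding and cDNA lengths. Of these genes, 15313 had more than 1 model and 455 lay on unplaced scaffolds. RPKM is the number of hits scaled by transcript length and by the total hits of the library. Multiplied by the cDNA length, the low values were whole multiples of what 1 hit is worth in each library (100% within 0.05 of a whole hit), so the summed hits per library could be recovered. They ran from 83123127 to 192296346. Whether a hit shared by several models of a gene was counted for each of them is not given, so these totals may exceed the number of reads. RPKM is not a count, and no count model was used for the main results.

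Each gene was represented by its model with the longest cDNA. Genes with an RPKM of at least 1 in at least 3 of the 12 libraries were tested, which left 30775. Log2(RPKM + 1) was fitted with limma 3.58.1 in R 4.3.3, with 1 mean per group, an intensity trend and a spread shared by all 12 libraries, and p-values were adjusted by the Benjamini-Hochberg method. A gene was called at an adjusted p under 0.05, two-sided. Fold changes are on the log2(RPKM + 1) scale, which understates changes of low genes. The 5 contrasts were black saddle minus yellow region in each line, Clark 18a minus Clark 8 in each region, and the difference between the 2 region differences (the interaction). Exact permutation of 3 libraries against 3 cannot give a p below 0.1, so p-values come from limma only. The libraries are biological repeats per the labels, which do not say whether they came from separate plants, so p-values measure the spread between these samples.

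Neither the deposited table nor the reference table given here (assembly Glycine_max_v4.0) pairs the Glyma identifiers with gene names, and 0 of the reference table's lines carry such an identifier. The identifiers of AGO5 and of 14 chalcone synthase genes were written down before the data were examined, from knowledge of the literature on these lines, and were checked here only by coding length (890 amino acids for AGO5, 388 or 389 for the chalcone synthases). Their names therefore rest on that recollection and not on a table. Other genes are given by identifier only. Gene lists defined by annotation words had also been fixed, and could not be used because the table holds no annotation text. The chalcone synthase list was the 1 list with at least 3 members that could be tested. Further lists of recalled identifiers were drawn up later and tried, and these are not reported, since no table names their members; neither is a check of repeat 3 that rested on 1 of them, whose outcome went against tissue carried over. Because 9 lists were tried, the p of each list test is also given multiplied by 9.

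The list was tested with limma's camera at a preset inter-gene correlation of 0.01, and again with an estimated correlation (0.557 in each contrast) and with fry. With 1 list reported, its adjusted p equals its p. Chalcone synthase members share near-identical sequence, so the value of a single member is uncertain. For the same reason, a count of members is not a count of independent genes. Their RPKM was therefore also summed per library, and log2(sum + 1) was added to the limma model of all genes for all 14 members, for the 8 on chromosome 8, and for the pair Glyma.01G228700 and Glyma.11G011500. The last 2 sums were added after the data were examined. If a read was counted for each copy it matched, a sum holds it more than once. The plan had been a separate limma model of the sums. It was replaced, after its results were seen, because 3 nested sums are too few to estimate a shared variance. Its p-values depend on which sums enter it: together with sums of the lists not reported, it did not call the 14 members between the lines in black. That model and one in which each sum kept its own variance, the latter an ordinary linear model, are given as alternatives. Both adjust p over the 3 sums alone, where the main model adjusts over all genes. Their smaller p-values for the main differences are therefore not like for like.

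The rule for named genes, fixed before the data were examined, took AGO5 and the chalcone synthase members whatever their result, and the 10 largest rises and falls per contrast among called genes whose libraries did not overlap between groups (no such condition for the interaction). Of the largest changes, at most 2 rises and 2 falls are given per contrast, because these genes have no names here. Glyma.08G110800 is also given, with the neighbouring genes.

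Libraries with the same repeat number deviated together from their group means. Between the regions of 1 line, the correlation of same-numbered residuals across genes was 0.52 to 0.75, against -0.61 to 0.13 for other pairs. Between the lines in 1 region it was 0.12 to 0.5, against -0.44 to 0.29. Across the lines the highest values came from repeat 3. For repeats 1 and 2 in 1 region they were 0.12 to 0.33 with the same number and 0.031 to 0.29 with the other. The numbers from the labels were therefore taken to pair the regions of a line, but across the lines repeats 1 and 2 are not clearly paired. Models with the repeat number as a block (within each line for regions, across the lines for lines) were run as alternatives, and the block across the lines carries that limit. The other alternatives were pseudocounts of 0.1 and 0.5, no filter on low values and a minimum RPKM of 5, median of ratios rescaling, quantile normalization, no trend, array weights, a log2 fold change of at least 1, each library left out in turn, the libraries of repeat 3 left out, and only the 6 libraries compared. Added after the data were examined were the highest-RPKM and the lowest-numbered model per gene, and limma voom on the recovered hits with and without the block.

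The model was tested on simulated data with the same 30775 genes, depths and spread, in which 100 genes changed by 1 and 100 by 2 on the log2 scale. For a change of 1 it recovered 60% in the Clark 8 region contrast, 48% in the Clark 18a region contrast, 53% between the lines in black, 44% between the lines in yellow and 31% in the interaction. For a change of 2 it recovered 87%, 87%, 83%, 83% and 75%, in the same order. The unchanged genes gave 10, 8, 10, 6 and 9 calls. The noise came from each gene's spread, drawn independently for each library, with the sampling noise of hits on top. It lacked the joint deviation of same-numbered libraries. These rates and calls therefore hold for independent libraries and need not hold for the data. Tables were prepared with Python 3.11.15, pandas 2.3.3 and numpy 2.4.6, and figures with matplotlib 3.10.9.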

Results

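Transcript levels were measured by RNA-seq in the seed coats of 2 soybean lines whose seeds carry a black saddle on a yellow coat. Clark 8 has the alleles i-k and K1, and Clark 18a has i-i and k1. The I locus restricts pigment through silencing of chalcone synthase, the first committed enzyme of flavonoid synthesis, and the series title ties K1 to Argonaute5, a protein that binds small RNAs. The coats were still immature when the future black and yellow regions were separated, and each of the 4 groups had 3 libraries. Summed hits per library ran from 83123127 to 192296346. The 4 libraries of Bio Repeat 3 were the shallowest, with at most 89505760, and their library numbers form a series of their own, whereas repeats 1 and 2 were numbered by line. The lines differ at both loci, so a difference between them cannot be assigned to K1 alone.

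The region was the main axis of variation. In a principal component analysis of the tested genes the first component held 44.2% of the variance and parted black from yellow libraries. The second held 20.9% and set repeat 3 apart in each group. Pairs of libraries within a group correlated at 0.951 to 0.978 for repeats 1 and 2, and at 0.871 to 0.954 where 1 of the pair was repeat 3. The repeat 3 libraries of the 2 lines correlated with each other at 0.96 in black and 0.982 in yellow.

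**Figure D1:**
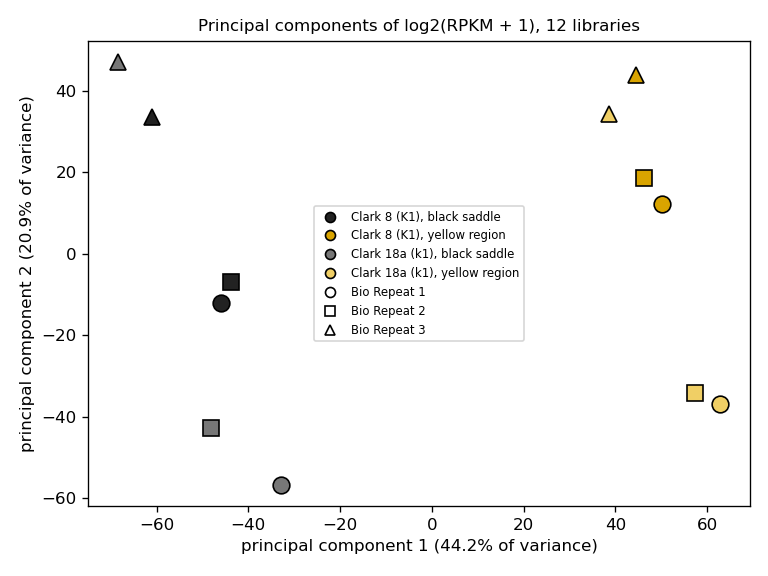
Scores of the 12 libraries on principal components 1 and 2 of log2(RPKM + 1), both in arbitrary units, with the share of variance on each axis; color gives the group and marker shape the Bio Repeat. Component 1 (44.2%) parts the regions, and the repeat 3 libraries (triangles) lie at the top of component 2 (20.9%).

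AGO5 (Glyma.11G190900), the gene of the series title, was lower in Clark 18a than in Clark 8 in the yellow region. Its level there was 7.62 ± 2.59 RPKM in Clark 8 and 1.14 ± 0.454 in Clark 18a (mean ± SD, n = 3 each), a ratio of means of 6.69. In limma it fell by 1.98 on the log2 scale (SE 0.266, adjusted p = 0.0209), and it was lower in Clark 18a in all 3 repeats, by log2 differences of -2.40, -2.44 and -1.10. In the black saddle it measured 3.94 ± 1.11 RPKM in Clark 8 and 1.75 ± 0.663 in Clark 18a, and the difference of -0.85 did not pass (adjusted p = 0.752), although the 3 repeats gave -0.87, -0.85 and -0.83. Within Clark 8, black minus yellow was -0.78 (adjusted p = 0.0805), with -1.22 and -1.24 in repeats 1 and 2 and 0.13 in repeat 3, and within Clark 18a it was 0.35 (adjusted p = 0.428). The interaction was 1.13 (SE 0.377, adjusted p = 1). The call in yellow was lost without Clark 8 yellow repeat 1 (adjusted p = 0.118) or 2 (0.136), or without Clark 18a yellow repeat 1 (0.111) or 2 (0.138), and with only the 6 libraries compared (0.127), and over all alternatives the adjusted p ran from 5.19e-05 to 0.138. The region difference in Clark 8 passed with the repeat as a block (adjusted p = 0.0475), without Clark 8 yellow repeat 3 (0.0212), without all repeat 3 libraries (0.00121), with array weights (0.000166) and with the block and voom (0.031), and the black difference between lines passed without repeat 3 (0.00996). Over all alternatives these ran from 0.000166 to 0.262 and from 0.00996 to 1. Without repeat 3 the libraries were numbered by line, so a line effect and a library set effect cannot be told apart there. The repeat 3 pair, numbered together, gave -0.83 in black and -1.10 in yellow, the latter smaller than in repeats 1 and 2.

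**Figure D2:**
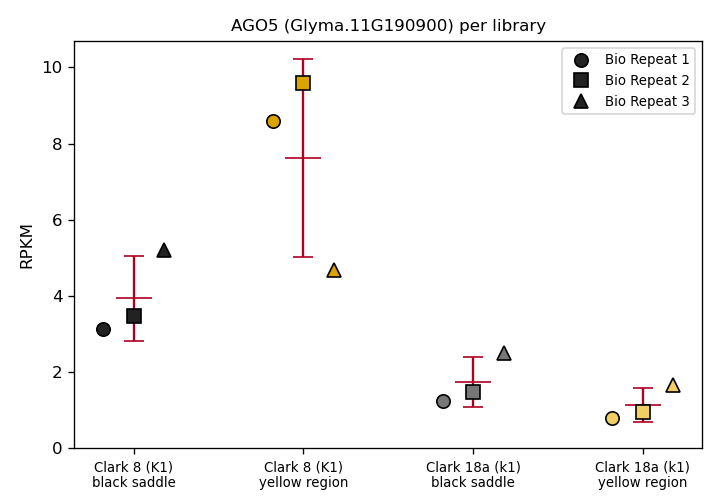
AGO5 level in RPKM (linear axis) in each of the 12 libraries by group, with marker shape giving the Bio Repeat and red lines the mean and SD of 3 libraries. The Clark 8 yellow libraries run from 4.68 to 9.59, and the 3 Clark 18a yellow libraries from 0.81 to 1.66.

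In Clark 8, chalcone synthase genes were higher in the black saddle than in the yellow region. The summed RPKM of the 14 members was 660 ± 35.9 in black and 98.8 ± 38.1 in yellow, a ratio of 6.68 (limma log2 difference 2.81, SE 0.333, adjusted p = 0.000277, higher in 3 of 3 repeats). Most of it came from Glyma.01G228700, which rose from 36.2 ± 17.6 to 301 ± 29.7 RPKM (adjusted p = 0.000365), and Glyma.11G011500, which rose from 23.1 ± 11 to 186 ± 9.41 (adjusted p = 0.000364). The 8 members on chromosome 8 together rose from 36.9 ± 9.58 to 163 ± 3.78 RPKM (adjusted p = 0.000137). Of 13 members tested, 12 rose and 0 fell, and 13 passed when adjusted over the list alone. The 8 on chromosome 8 are near-identical copies, so these are not counts of independent genes. At the preset inter-gene correlation of 0.01, camera placed the list above other genes (adjusted p = 1.51e-19, p times 9 lists = 1.36e-18). With the estimated correlation of 0.557 the camera p was 0.00862, or 0.0776 times 9 lists, which does not pass. The member that did not pass, Glyma.09G075200, lay at 1.23 ± 0.337 RPKM in black and passed in 6 alternatives, among them the block (adjusted p = 0.00225) and the omission of Clark 18a black repeat 3 (0.0225), with a range of 0.00106 to 0.196 over all alternatives.

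Beyond this family, limma called 4266 of 30775 genes (13.9%) between the regions of Clark 8, 2311 higher and 1955 lower in black. The largest rises were Glyma.09G043500, from 2.57 ± 2.83 to 245 ± 108 RPKM, and Glyma.09G084200, from 0.276 ± 0.212 to 102 ± 38.8. The largest falls were Glyma.09G198900, from 147 ± 38.6 in yellow to 3.94 ± 2.68 in black, and Glyma.17G030100, from 51.5 ± 13.3 to 0.923 ± 0.322. Their adjusted p-values were 4.69e-05, 4.52e-06, 0.00016 and 3.03e-06. The libraries of the regions did not overlap for 4248 of the called genes. This adds no support, since the genes were chosen by p in the same libraries, and the 10% given by chance holds only for genes not so chosen. The count was 11431 with the block (4265 of the 4266 among them), where the balance turned to 4916 higher and 6515 lower, as it did with array weights (4949 and 6460) and the block with voom (4732 and 7154). It was 4352 without repeat 3, 2549 without yellow repeat 2, 2787 without black repeat 2 and 2804 without black repeat 1.

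In Clark 18a, the pair Glyma.01G228700 and Glyma.11G011500 was again higher in black, while the chromosome 8 members did not pass. The pair summed to 358 ± 135 RPKM in black and 57.6 ± 13.2 in yellow (limma log2 difference 2.57, SE 0.399, adjusted p = 0.00149). The chromosome 8 members summed to 35.6 ± 6.64 in black and 24.9 ± 5.8 in yellow, a log2 difference of 0.51 (SE 0.229) that was above 0 in 3 of 3 repeats and did not pass (adjusted p = 0.175), except with the block (0.0488; 0.0488 to 0.443 over all alternatives). The sum of all 14 rose from 85.3 ± 8.16 to 398 ± 142 RPKM (adjusted p = 0.00148). Of 13 members tested, 3 rose and 0 fell, with 7 passing when adjusted over the list alone. The camera test gave an adjusted p of 0.000122 (p times 9 lists = 0.0011), and the p was 0.18 with an estimated correlation and 0.0869 by fry times 9 lists, so the list call was lost there. The third riser, Glyma.05G153200, went from 1.44 ± 0.196 to 2.52 ± 0.406 RPKM (adjusted p = 0.0207), and its call ended without black repeat 2 (0.0792), yellow repeat 1 (0.08) or yellow repeat 3 (0.0595) and without repeat 3 as a whole (0.0502), with a range of 0.00485 to 0.0934 over all alternatives. With the block, among other alternatives, 6 of the chromosome 8 members and Glyma.01G091400 also passed, with adjusted p-values from 0.0208 to 0.0479.

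Across all genes, limma called 4607 of 30775 (15%) between the regions of Clark 18a, 2726 higher and 1881 lower in black. The largest rises were again Glyma.09G043500, from 1.09 ± 1.39 to 171 ± 35.1 RPKM (adjusted p = 3.62e-05), and Glyma.09G084200, from 0.222 ± 0.106 to 106 ± 60.3 (adjusted p = 4.07e-06). The largest fall, Glyma.03G035800 (adjusted p = 0.0409), lost its call when any of 9 of the 12 libraries was left out, with adjusted p-values up to 0.106 (without Clark 18a yellow repeat 2). The next, Glyma.18G055300, went from 16.6 ± 7.01 in yellow to 0.157 ± 0.0792 in black (adjusted p = 0.00183; 0.0572 with voom). The libraries did not overlap for 4552 of the called genes, which again follows largely from the choice by p in the same libraries. The 10% given by chance holds only for genes not so chosen. The count was 12016 with the block (all 4607 among them), 6097 higher and 5919 lower, and with voom as well the balance turned to 5897 higher and 6183 lower. It was 4716 without repeat 3, 2952 without yellow repeat 2, 2985 without yellow repeat 1 and 2894 with only the 6 libraries compared.

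The region differences of the lines were alike across genes. Their log2 differences correlated across the 30775 genes at r = 0.881 (Spearman 0.829), with genes not being independent replicates and no library shared. Of the called genes, 1982 were higher in black in both lines, where independent lists would share 204.7, and 1128 were lower in both, where 119.5 would be shared. Same-numbered libraries of the lines deviated together, most of all in repeat 3, so the lists are not fully independent. Only 1 gene was called in opposite directions. The chromosome 8 chalcone synthases lay off this trend, with rises of 1.80 to 2.03 in Clark 8 and differences of at most 0.57 in Clark 18a.

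**Figure D3:**
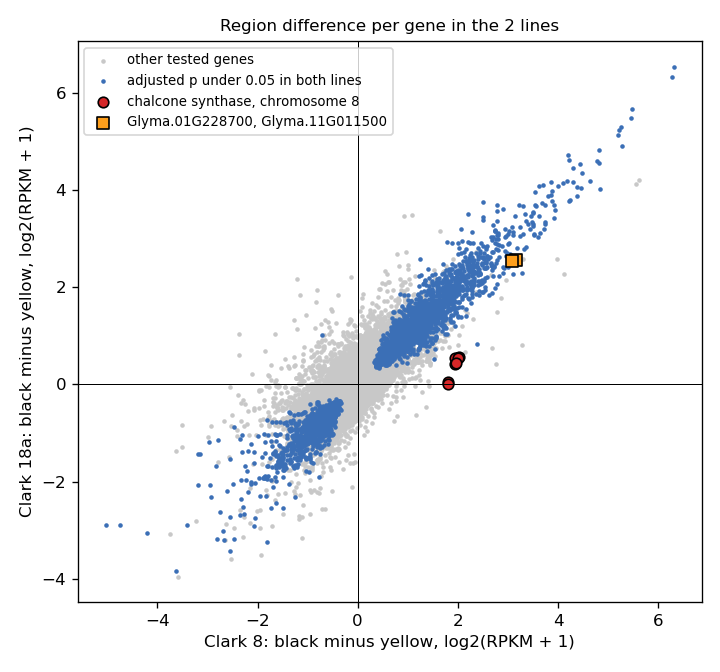
Black minus yellow difference of each tested gene on the log2(RPKM + 1) scale in Clark 8 (horizontal axis) and Clark 18a (vertical axis), with genes called in both lines in blue. The pair Glyma.01G228700 and Glyma.11G011500 (squares) lies on the common trend (r = 0.881), and the 8 chromosome 8 chalcone synthases (red) lie below it.

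Between the lines, the chromosome 8 chalcone synthases were lower in the black saddle of Clark 18a. Their sum was 163 ± 3.78 RPKM in Clark 8 and 35.6 ± 6.64 in Clark 18a, a ratio of 4.57, and fell by 2.18 on the log2 scale (limma SE 0.229, adjusted p = 0.00308), with a range of 1.22e-06 to 0.033 over the alternatives. The 3 repeats gave -2.48, -2.00 and -2.06. All 8 members passed, with differences of -2.06 to -1.68 and adjusted p-values of 0.00122 to 0.0035, and Glyma.05G153200 fell from 6.95 ± 0.568 to 2.52 ± 0.406 RPKM (adjusted p = 0.00413; 0.148 with only the 6 libraries compared and 0.0627 at a minimum RPKM of 5). The pair Glyma.01G228700 and Glyma.11G011500 measured 487 ± 39 in Clark 8 and 358 ± 135 in Clark 18a, a difference of -0.51 (SE 0.399) that did not pass (adjusted p = 0.975). The chromosome 8 members made up 24.7% ± 1.92 of the chalcone synthase RPKM in Clark 8 black and 9.36% ± 1.84 in Clark 18a black. In the list, 9 of 13 fell and 0 rose, and 10 passed when adjusted over the list alone. The 8 on chromosome 8 are near-identical copies, so these are not counts of independent genes. At the preset inter-gene correlation of 0.01, camera gave an adjusted p of 1.29e-41 (p times 9 lists = 1.16e-40). With the estimated correlation of 0.557 the camera p was 0.000855 (0.00769 times 9 lists). The sum of all 14 members differed by -0.79 (SE 0.333) and did not pass (adjusted p = 0.881). Adjusted over the 3 sums alone, it did not pass with its own variance (0.0796) but did in the separate moderated model (0.0463; 0.0463 to 1 over all alternatives). A separate model had been planned, but not with these 3 sums.

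**Figure D4:**
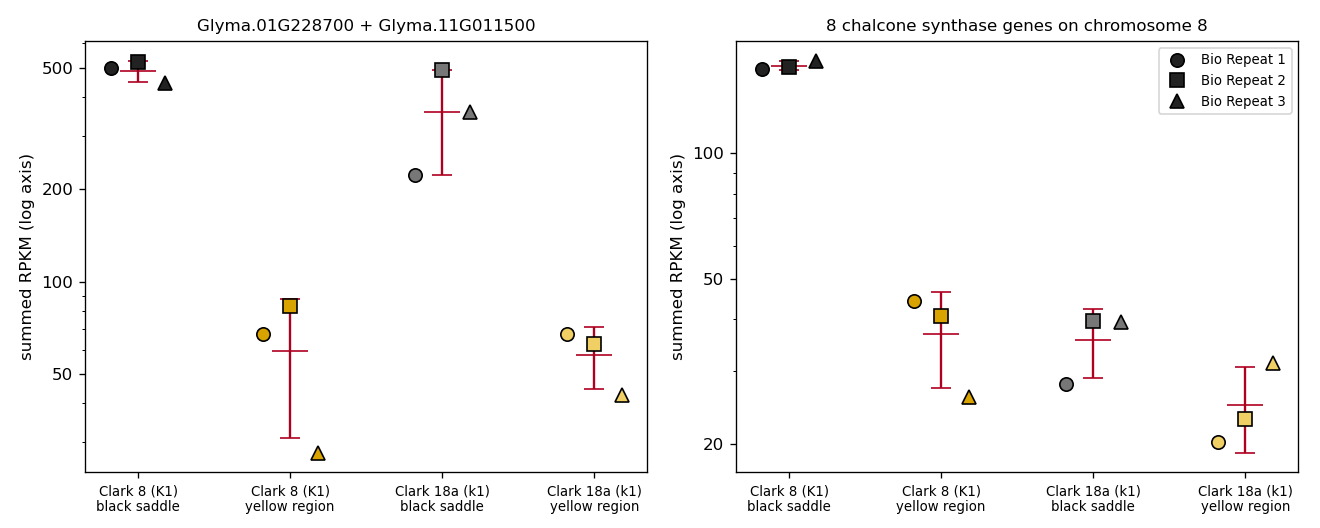
Summed RPKM per library (log axes, different ranges) of the pair Glyma.01G228700 and Glyma.11G011500 (left) and of the 8 chromosome 8 chalcone synthase genes (right) by group, with marker shape giving the Bio Repeat and red lines the mean and SD of 3 libraries. On the right, the Clark 18a black libraries (27.9 to 39.5) lie below the Clark 8 black libraries (159.9 to 167), and on the left 1 of them overlaps that group.

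Limma called 25 genes in all between the lines in black, 6 higher and 19 lower in Clark 18a. Among the rises were Glyma.15G115300, from 1.15 ± 0.563 to 31 ± 15.3 RPKM (adjusted p = 0.00318; 0.116 with only the 6 libraries compared and 0.0508 with voom), and Glyma.14G033900, from 3.86 ± 0.822 to 19.9 ± 2.21 (adjusted p = 0.00122). The largest falls were Glyma.11G073700, from 18.1 ± 1.04 to 2.66 ± 0.112 RPKM (adjusted p = 2.73e-05), and Glyma.08G110400, from 27.4 ± 2.86 to 5.65 ± 1.13 (adjusted p = 0.00122). By identifier the latter lies between the listed chalcone synthases Glyma.08G110300 and Glyma.08G110500. Its levels were close to those of Glyma.08G110500 (25.2 ± 1.66 in Clark 8 black and 5.33 ± 1.06 in Clark 18a black), and reads shared between them were not tested. All 25 had libraries that did not overlap, but they were chosen by p in the same libraries, so this adds no support. The 10% given by chance holds only for genes not so chosen. The count was 52 with the block (21 higher, 31 lower), 1240 without repeat 3 and 45 without Clark 18a black repeat 3, and the 25 genes were among the first 2 of these in full. The excess of falls did not hold throughout: 944 were higher and 296 lower without repeat 3, 181 and 57 with block and voom, and 38 each with array weights.

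In the yellow region, no chalcone synthase member passed between the lines in the model of all 12 libraries. The sum of the 14 was 98.8 ± 38.1 RPKM in Clark 8 and 85.3 ± 8.16 in Clark 18a (limma log2 difference -0.13, SE 0.333, adjusted p = 0.926), and it turned to 0.02 without Clark 8 yellow repeat 1 and 0.09 without Clark 8 yellow repeat 2. The chromosome 8 members differed by -0.54 (limma adjusted p = 0.346, with a range of 0.0215 to 0.874 over all alternatives). The 3 repeats gave -1.09, -0.79 and 0.26, so the sign turned in repeat 3. Their sum passed without repeat 3 (-0.94, adjusted p = 0.0215). There the libraries were numbered by line, so a line effect and a library set effect cannot be told apart. Of 13 members 0 passed, and 3 did when adjusted over the list alone. Of the chromosome 8 members, 6 passed as lower in Clark 18a without repeat 3 (adjusted p = 0.0168 to 0.0226) and with array weights (0.00184 to 0.00366). The camera test gave an adjusted p of 0.0085, but p times 9 lists was 0.0765, the p was 0.344 with an estimated correlation, and fry gave 0.192.

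Limma called 127 genes between the lines in yellow, 33 higher and 94 lower in Clark 18a, AGO5 among the latter. The largest rises were Glyma.10G113600, from 0.159 ± 0.129 to 9.55 ± 1.43 RPKM (adjusted p = 6.36e-05), and Glyma.10G092500, from 0.168 ± 0.106 to 7.51 ± 4.4 (adjusted p = 0.00297; 0.0928 with only the 6 libraries compared). The largest falls, Glyma.11G198500 and Glyma.15G086100 (both adjusted p = 0.0325), lost their calls when any of 7 and 6 of the 12 libraries was left out, with adjusted p-values up to 0.178 (without Clark 18a yellow repeat 2). All 127 had libraries that did not overlap. They were chosen by p in the same libraries, so this adds no support, and the 10% given by chance holds only for genes not so chosen. In both regions 11 genes were called, 4 higher and 7 lower, where independent lists would share 0.00643 and 0.058. The lists are not independent, since same-numbered libraries of the regions of a line deviated together. The count depended on single libraries. It was 14 without Clark 8 yellow repeat 1 or 2, 15 and 17 without Clark 18a yellow repeat 2 and 1, 22, 37 and 64 without Clark 8 black repeat 2, 1 and 3, and 46 without Clark 18a black repeat 2. It rose to 421 without Clark 8 yellow repeat 3, 509 without Clark 18a yellow repeat 3 and 3636 without all repeat 3 libraries, and was 208 with the block. The excess of falls shrank to 88 higher and 120 lower with the block, and turned to 1926 higher and 1710 lower without repeat 3 and to 1264 and 741 with block and voom.

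The interaction asked whether the region difference itself differed between the lines. For the chromosome 8 chalcone synthase sum it was -1.64 on the log2 scale and did not pass in the limma model of all genes (SE 0.324, adjusted p = 0.481). It passed when the sum kept its own variance and p was adjusted over the 3 sums alone (adjusted p = 0.00354; 0.00354 to 1 over all alternatives). The main model adjusted over all genes, so these adjusted p-values differ in more than the variance. The sum of all 14 members gave -0.66 (adjusted p = 1). Among 13 members, 1 was called (Glyma.08G109400, -1.80, adjusted p = 0.0434), and 10 passed when adjusted over the list alone. The 8 on chromosome 8 are near-identical copies, so the 10 are not independent genes. The list median was -1.43, and camera at the preset inter-gene correlation of 0.01 gave an adjusted p of 9.6e-45 (p times 9 lists = 8.64e-44). With the estimated correlation of 0.557 the camera p was 0.000671 (0.00604 times 9 lists). Across all genes 5 were called, 3 above and 2 below 0, with 767 at an unadjusted p under 0.05. No change would give 1539 if the libraries were independent, but same-numbered libraries of the regions of a line deviated together (r = 0.52 to 0.75), so the model without the block overstates the error of this contrast and no change would give fewer. With the block, 3146 genes had an unadjusted p under 0.05. The count of called genes was 1 with the block and 1 without repeat 3. It fell to 0 without Clark 8 black repeat 1, 2 or 3, Clark 8 yellow repeat 1 or 2, Clark 18a black repeat 3, or Clark 18a yellow repeat 1 or 2, and to 3 and 1 without Clark 18a black repeat 1 and 2.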

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

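The tests of the chromosome 8 members against the pair Glyma.01G228700 and Glyma.11G011500 and against genes called in Clark 8 in this part were chosen only after the result was seen. In the interaction model, which tests whether black minus yellow differs between Clark 18a and Clark 8, limma called 5 genes. Glyma.03G074000 gave 2.98 (adjusted p = 0.0286; 0.0431 with the block) and was 8.97 ± 2.64 RPKM in Clark 8 yellow against 0.576 ± 0.34 to 1.4 ± 0.478 in the other groups. Glyma.10G002200 gave 2.49 (adjusted p = 0.0286; 0.0681 with the block). Glyma.02G002100 gave 1.56 (adjusted p = 0.0483; 0.0847 with the block). Glyma.11G073700 gave -1.54 (adjusted p = 0.0286; 0.085 with the block), and the chalcone synthase Glyma.08G109400 gave -1.80 (adjusted p = 0.0434; 0.0823 with the block). The chalcone synthase list as a whole had a median of -1.43 (camera adjusted p = 9.6e-45; 4.15e-25 with the block). Both p-values assume an inter-gene correlation of 0.01. With the estimated correlation of 0.557 the camera p was 0.000671, or 0.00604 times 9 lists. Each of the 5 calls was lost when any 1 of 9 to 11 of the 12 libraries was left out, with adjusted p-values up to 0.156 for Glyma.03G074000, Glyma.10G002200 and Glyma.11G073700 (without Clark 8 black repeat 2), 0.197 for Glyma.08G109400 (without the same library) and 0.271 for Glyma.02G002100 (without Clark 18a yellow repeat 1).

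The chalcone synthase genes on chromosome 8 were low in the black saddle of Clark 18a, while the pair on chromosomes 1 and 11 was not called between the lines. Reads shared with that pair at the same rate in both lines would keep the ratio of the 2 sums alike. That ratio was 0.105 in Clark 18a black and 0.336 in Clark 8 black. The highest Clark 18a library (0.125) lay under the lowest Clark 8 library (0.309). Since the ratio restates the 2 sums already compared, it speaks only against sharing at an equal rate as the whole cause. Sharing at a rate that differs between the lines was not tested. A smaller share of black tissue in the Clark 18a pieces would lower black-region genes in general, but the 2299 other genes called higher in black in Clark 8 had a median line difference of 0.00829 (quartiles -0.152 and 0.178), and 99.8% of them lay above the highest chromosome 8 member (-1.68). The 446 of these that rose in Clark 8 by at least 1.8, as the chromosome 8 members did, had a median of -0.0541 (quartiles -0.302 and 0.181), with 99.3% above that member. The set planned beforehand, 1979 genes called higher in black in both lines (median 0.0223), leaves out genes that fell in Clark 18a black and is not relied on. Sequence differences between the lines' copies and the reference stay open, as does the exchange of reads among the 8 members. That exchange leaves their sum as it is only if each read was counted once, and how reads with several hits were treated is not given. A biological difference between the lines, which differ at both I and K1, also stays open and was not tested.

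The Bio Repeat 3 libraries stood apart in all 4 groups, and leaving them out raised the calls between the lines from 25 to 1240 in black and from 127 to 3636 in yellow. Lower depth was tested by thinning all libraries to the shallowest, after which repeats 1 and 2 still correlated best within their group in 4 of 4 groups. Of genes called between the lines from repeats 1 and 2 alone, 50.2% kept their sign in the repeat 3 pair in black and 67.6% in yellow, where 47.6% and 56.3% of all tested genes did, with r = 0.0106 and 0.265 over all genes. For the region contrasts of Clark 8 and Clark 18a the shares were 98.7% and 95.9%, where 79.2% and 77.7% of all tested genes did. The median size of the called log2 differences was 1.01 and 0.827 for the lines in black and yellow and 0.924 and 0.938 for the regions. The low share in black is in line with differences between library sets, since the libraries of repeats 1 and 2 were numbered by line and those of repeat 3 together, but the share in yellow lay between the bounds set beforehand, so a set effect and a line effect cannot be told apart in repeats 1 and 2. Differences in seed stage stay open. Tissue carried over cannot be judged from the genes that can be named here. The 1 check made of it went against it, but is not reported because its genes have no names here. No conclusion is drawn from that check, so tissue carried over stays open.

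Other splits of the same libraries were counted for each of the 5 counts. With 3 libraries against 3 there are 10 splits, too few for a share under 0.05, and in each contrast 1 of the 10, the real one, gave a count as large. The real split and the highest other gave 4266 and 1 for the regions of Clark 8, 4607 and 8 for the regions of Clark 18a, 25 and 0 between the lines in black, 127 and 0 between the lines in yellow, and 5 and 0 for the interaction. Among the 4 splits that part as many same-numbered pairs, the highest other was 0 in every contrast.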

How the results depend on the processing

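Models per gene by highest RPKM or lowest number, voom with and without the block, the sums in the model of all genes or with their own variance (a separate moderated model had been planned), p times 9 lists, all alternatives of the 2 partial sums, and for AGO5 and the chalcone synthase sum those other than pseudocount 0.1, rescaling, block and single libraries left out, were chosen after the data were examined. Alternatives were run for counts, levels, sums, list tests and correlation. Of these, 599 left the result as it was, 11 moved it past the threshold and 5 short of it. A further 6 turned the sign and 73 moved a count of genes or lists. A count within 1.5 times and a correlation within 0.1 were taken as unchanged. Other results were so taken if they stayed on the same side of the threshold, called or not. Counts below are for the regions of Clark 8, the regions of Clark 18a, the lines in black, the lines in yellow and the interaction, where they moved by over 1.5 times. A minimum RPKM of 5 gave 1958, 2191, 14, 12 and 0, with fewer genes tested. Without a filter the last 3 were 48, 200 and 10. The replicate block gave 11431, 12016, 52, 208 and 1; with voom 11886, 12080, 238, 2005 and 1. Voom alone gave 16 in black and 0 for the interaction. Array weights gave 11409 (Clark 8), 76, 7318 and 28. A log2 change of at least 1 gave 1854, 2004 and 84 (yellow). Pseudocount 0.1 gave 35 (yellow) and 0 (interaction), and 0.5 gave 2 (interaction). Quantile normalization gave 73 and 1 for the last 2. Without repeat 3 the last 3 were 1240, 3636 and 1. With only the 6 libraries compared, fewer samples gave 2894, 11 and 3 in the middle 3. Leaving out 1 library gave 2549 to 4809, 2952 to 5693, 17 to 45, 14 to 509 and 0 to 7.

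AGO5 between the regions of Clark 8 passed with array weights (-1.16), the block (-0.78), the block with voom (-0.997) and without repeat 3 (-1.23), and ranged from -1.05 to -0.60 with 1 library left out. Between the lines it passed in black without repeat 3 (-0.86), and failed in yellow with only the 6 libraries (-1.98), with a leave-one-out range of -2.26 to -1.81. The sum of all 14 chalcone synthases passed between the lines in black in a separate moderated model (-0.79, adjusted p = 0.0463) but not with its own variance (0.0796), and in yellow ranged from -0.497 to 0.093 with 1 library left out. The chromosome 8 sum passed in the Clark 18a regions with the block (0.51), in the yellow lines without repeat 3 (-0.94), and in the interaction with its own variance or a separate moderated model (-1.64 in both). Both of these models adjusted p over the 3 sums alone. The passes between the lines without repeat 3, for AGO5 and for this sum, rest on libraries numbered by line. A line effect and a library set effect cannot be told apart there. The pair's sum in the yellow lines, 0.07 and not called, turned to -0.199 without repeat 3 and ranged from -0.398 to 0.381 with 1 library left out. The number of lists passing, 1 in each contrast, was 0 in the Clark 8 regions with an estimated correlation times 9 lists. It was 0 in the Clark 18a regions with an estimated correlation, alone or times 9, and by fry times 9. In the yellow lines it was 0 with camera times 9, and with an estimated correlation or fry, alone or times 9. The correlation of region differences stayed at 0.821 to 0.885 with 1 library left out.

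Among named genes, 2062 alternatives left the call as it was, 50 gained one, 129 lost one and 24 turned sign, the last for values that were not called. Glyma.08G109400 in the Clark 18a regions turned from -0.00151 to 0.00285 (pseudocount 0.1), 0.00032 (pseudocount 0.5), 0.00963 (rescaling), 0.00395 (quantile), 0.0989 (array weights) and 0.0892 (without repeat 3), and ranged from -0.0927 to 0.157 with 1 library left out. Glyma.08G109300 there ranged from -0.0493 to 0.202. Between the lines in yellow, array weights and the lack of repeat 3 gave -0.13 and -0.254 for Glyma.08G109300, -0.332 and -0.265 for Glyma.01G228700, and -0.176 and -0.0952 for Glyma.11G011500. Their leave-one-out ranges were -0.0913 to 0.207, -0.446 to 0.333 and -0.312 to 0.426. The cause of these changes was not tested. For AGO5, the sums, the lists and the genes named, the block changed no other call than those given here, in the report or with the interaction genes. Where leaving out a library left a group with 2, the shared spread of all groups was used. Depth limits low genes, since 3 hits on a 2 kb transcript correspond to 0.0078 to 0.018 RPKM.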

Other observations

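The count of neighbouring genes in this part, and the comparison with pairs of chalcone synthases, were chosen only after the result was seen. Genes called between the lines were not spread evenly over the genome. In the yellow region 125 of them lay on a chromosome, with 16 on chromosome 10 and 14 on chromosome 8, and 26 had another called gene within 10 tested genes along the identifiers. In black, 12 of 25 had such a neighbour, where random draws gave 0.371 on average, but 8 of the 12 were the chromosome 8 chalcone synthases, near-identical copies for which shared reads were not tested. Glyma.08G110400 and Glyma.08G111000, also called in black, lie among or next to these by identifier, so still more of the 12 come from this 1 stretch. Not every gene there fell. Glyma.08G110800, named after its values were seen, lies by identifier between the listed Glyma.08G110700 and Glyma.08G110900. It rose from 0.0411 ± 0.0491 RPKM in Clark 8 yellow to 5.5 ± 2.79 in Clark 18a yellow (limma adjusted p = 0.011). In black, where it was not called, it measured 0.0761 ± 0.105 in Clark 8 and 2.65 ± 1.63 in Clark 18a.

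In 10000 random draws of as many genes in yellow, the mean was 9.77 and only 5 draws reached 26, which argues against random placement. Reads shared between tandem copies stay open. Of the 14 neighbouring pairs in yellow, 0% had group means within 10% of each other, but that bound, set beforehand, decides nothing, since of the 28 pairs of near-identical chromosome 8 chalcone synthases only 5 met it. Shared reads or identical copies may also lie behind some calls elsewhere, since 2 pairs of called genes in yellow had RPKM within 1% in all 12 libraries. In 1 of them, Glyma.07G164400 and Glyma.07G172100, named after their values were seen, the genes lie 40 places apart among the tested genes and were called in both regions. Chromosome segments that differ between the lines, and a difference in how the lines' reads match the reference in such segments, stay open, and expression values alone cannot test them.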
